A study of Zea mays with 32 samples.

How the data were processed

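The measurements are RNA-seq counts per gene in 32 libraries from 2 primary roots of maize B73, wild type, at 7 days after germination. Per the labels' protocols, plantlets grew on germination paper at 26 °C with 12 h of light, both roots were aligned and pinned together and cut from the tip backwards into 16 slices, RNA was extracted with a Qiagen RNeasy Micro kit, and libraries were made with the Ovation RNA-Seq System V2, a kit that amplifies cDNA from small amounts of RNA. Amplified reads without molecular identifiers are not independent molecules; no identifiers are mentioned in the labels.

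The deposited table holds whole-number counts for 39510 gene identifiers and 32 libraries. Per the submitters' processing notes, Trimmomatic, kallisto 0.43 and DESeq2 were used by the authors; the notes give no roles or order. The genome build, the annotation, the way transcript values were summed to genes, the use of strand and whether the counts were rounded from estimates are not given in the sources used here. Where kallisto made the counts, reads shared by near-identical genes are divided between them by estimation, so the values of members of such families are uncertain. Of the identifiers, 39336 belong to the Zm00001d series and 174 to the GRMZM5G series. The files do not pair identifiers with gene names, and 0 of them matched the reference table of 49888 genes (assembly Zm-B73-REFERENCE-NAM-5.0), which was therefore not used. For this reason the 26 gene lists fixed before the data were examined were not tested. Of the rule for naming genes, the requirement of a gene name was dropped. Its other parts were kept: adjusted p under 0.05, a log2 change of at least 1, a mean of at least 10 CPM over the 32 libraries, the same direction in each root, then the highest and lowest changes. In slices 13 to 16 against slices 1 to 4, 3466 genes met it among those that were higher and 2362 among those that were lower, and 2 of each are given.

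Each library was assigned to its slice and root from its title; 0 columns of the table were left without a sample. Replicates are the 2 roots. The slices of a root are not independent of each other, and p-values measure the spread between 2 roots cut together. Libraries with the same letter come from the same root per the labels, so the letters pair the samples. The deviations of 2 slices of a root from their slice means had a median correlation across genes of 0.143 over 120 pairs of slices (−0.02 to 0.376), 116 of them positive and 85 over 0.1. No libraries were identical.

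Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by slice (minimum count 10, minimum total 15), which left 19587 genes and removed 8493 all-zero identifiers among others, and the quasi-likelihood fit (robust, with the newer dispersion step, legacy = FALSE) with 16 slices as groups over all 32 libraries and no block. The choice of the newer step was made after the data were seen, for run time, and the older step is among the alternatives. Contrasts set means of slice coefficients against each other: slices 13 to 16 against 1 to 4, each further block of 4 slices against the block before it, slice 1 against slices 2 to 4, and the 15 steps between neighbours. A joint F test asked whether a gene varied between slices. The roots were compared in a model with slice and root, and the difference between the roots in the change from front to back with root by block of 4 slices as 8 groups, in which the 4 slices of a block stand in as replicates. The blocks are a split by slice number, not developmental zones. Adjusted p-values are Benjamini-Hochberg over the genes tested, calls are at an adjusted p under 0.05, and the SE of a log2 change is its size over the square root of F. Levels are CPM with TMM scaling; log2 CPM used a prior count of 2. The fold of a gene with no count in a group was computed against 3 counts over the group. Intervals are 95%; those for shares are Wilson intervals. Depth was compared by the number of genes expected at 1000000 counts.

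The steps were tested on simulated data, with counts drawn from the real genes' mean levels and library sizes and 200 genes with a mean of at least 10 CPM changed. The simulated spread followed the trend of the data without slice 8 of root A. It was the same in every slice, with no deviations shared by the slices of a root. In the real data the coefficient of variation between the 2 libraries of a slice ran from 4.9% to 161.6%, with 86.2% in slice 1. The rates below hold for the simulated setting only. For slices 13 to 16 against slices 1 to 4, over 18620 simulated genes, 17.9% of 2-fold, 85.1% of 4-fold and 98.5% of 8-fold changes were recovered, and 8 of 142 calls were false. For slice 1 against slices 2 to 4, over 18540 genes, 1.5%, 25.4% and 53% were recovered, with 2 of 55 calls false, and for slice 1 to 2, over 18575 genes, 0%, 9% and 40.9%. The other steps were not simulated with changed genes. With no gene changed, the joint test over 18537 simulated genes still called 25 genes and gave 11.5% of p-values under 0.05, so it is somewhat liberal. The 5 contrasts of slice groups, the comparison of the roots and the root by block test called 0 genes there, with 4.1% to 8.6% of p-values under 0.05, and the 15 single steps called 0 or 1 gene each, with 3.8% to 10.6%.

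Alternatives planned before the data were examined were DESeq2's size factors, DESeq2 1.42.0 in place of edgeR, no filter, a mean of at least 10 CPM, TMM without the 100 most abundant genes, each library left out in turn, a replicate block (root as a term), blocks of 4 slices as groups, each root alone and a minimum of 2-fold. Added after the data were seen were the older dispersion step, the data without the 3 libraries with the fewest genes at 1000000 counts (slices 8, 1 and 12 of root A), slice 7 counted as 1 library, slice 1 left out of the first block, and comparisons of 2 slices with the next 2. The match of the roots was also run over all tested genes, and each single step without each library. With 1 library left out the smallest group holds 1 library, and the filter then passed 21083 to 21272 genes. Chance was checked with 99 random reassignments of the libraries to slices, 99 within each root and 99 random swaps of the root letters within slices, beside the real arrangement.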

Results

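Maize (Zea mays) roots of the inbred line B73, wild type, were cut from the tip backwards into 16 slices at 7 days after germination. A growing root carries its cap and dividing cells at the tip, and cells elongate and mature as they come to lie farther back, so position along the root behind the cap stands in for developmental age. The submitters describe the set as a profile of the root's developmental zones; the labels give each slice its number and assign no slice to a zone. Both roots, A and B, were aligned and pinned together before cutting, which gave 32 RNA-seq libraries with 1 library of each root per slice (n = 2 per slice). The libraries held 1008082 to 5681180 counts (median 1860465). The number of genes with a count ran from 8303 in slice 8 of root A to 22414, and was at least 13804 in the other libraries.

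The 2 roots gave close profiles in most slices. The correlation of log2 CPM (counts per 1000000 counts) across genes between the roots was 0.832 to 0.932 in the slices other than 1, 7 and 8. It was 0.979 in slice 7, 0.731 in slice 1 and 0.578 in slice 8. Genes are not independent replicates, so these values describe similarity only. Slice 8 of root A stood apart: at a common depth of 1000000 counts it held 8262 genes, against 13740 to 19840 in the other libraries. The libraries of slice 7 differed from each other by a chi-square of 1.5 per degree of freedom over genes, against 7.3 to 95.3 for the pairs of the other slices. Among genes with at least 1000 counts over the pair the slice 7 value was 5.7, above sampling noise but far below the 48.7 to 718.7 of the other slices. The slice 7 libraries were kept as 2 and counted as 1 in an alternative. Without slice 8 of root A, the first principal component held 42.9% of the variance and ran from slice 3 to slice 13 in root A, and slice 1 lay apart on the second component, which held 14.1%.

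**Figure D1:**
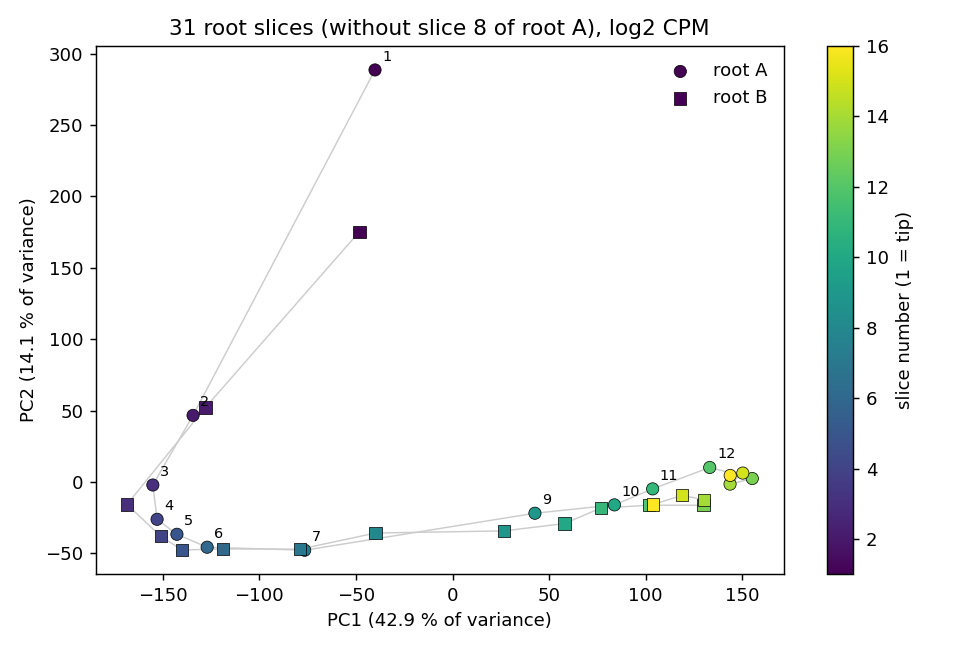
First 2 principal components (percent of variance on each axis) of log2 CPM for 31 libraries, coloured by slice number; circles are root A, squares root B, each point is 1 library, slices 1 to 7 and 9 to 12 of root A are numbered, and grey lines join neighbouring slices of a root. The slices follow 1 path from the tip to the back in both roots, with slice 1 at 288.62 (root A) and 175.31 (root B) on the second component.

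Genes in large number varied along the root. Of 19587 genes tested, 11934 (60.9%) varied between slices, and the median varying gene spanned 3.97 log2 units between its lowest and highest slice. A group of 1550 genes (13%) was highest in slice 1, 5149 (43.1%) in slices 2 to 8, 1816 (15.2%) in slices 9 to 12 and 3419 (28.6%) in slices 13 to 16. Slice 8 was the highest for 831 genes, for 1340 by root A alone and for 89 by root B alone. With slice 8 left out of the search for the highest slice, the groups held 1626, 4630, 2133 and 3545 genes, in that order. The slice 1 group fell sharply behind the tip: its median, centred per gene, was 2.86 in root A and 2.23 in root B in slice 1, and 0.55 and 0.75 in slice 2. The group of slices 2 to 8 was at −1.17 and −0.62 in slice 1, rose to 1.28 and 1.25 in slice 4, and was at −0.26 and −0.08 in slice 9, −1.14 and −0.64 in slice 12 and −0.73 and −0.2 in slice 16. The group of slices 13 to 16 climbed from −1.18 and −1.16 in slice 4 to 1.93 and 1.63 in slice 16. Slice 1 was also the slice of lowest expression for 3748 of the varying genes, followed by slice 8 (1689), slice 3 (1120) and slice 12 (983). Slices 1, 8 and 12 hold the libraries with the fewest genes at a common depth, all of root A, and slice 3 holds none of these. Whether low complexity of these libraries adds to the minima, and so to the median span of 3.97 log2 units, was not tested. The slice of highest expression lay within 1 slice in both roots for 52.8% of the varying genes. The groups are descriptive, since a highest slice carries no test. They were formed by the highest slice in these same data, so a peak there and lower medians elsewhere follow in part from the grouping. The joint test was edgeR's quasi-likelihood F test, with Benjamini-Hochberg adjustment. In the library of slice 8 of root A the medians of all 4 groups lay below those of its neighbours, and without that library 13290 genes varied. With an older dispersion step of the same test, 8675 genes varied.

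**Figure D2:**
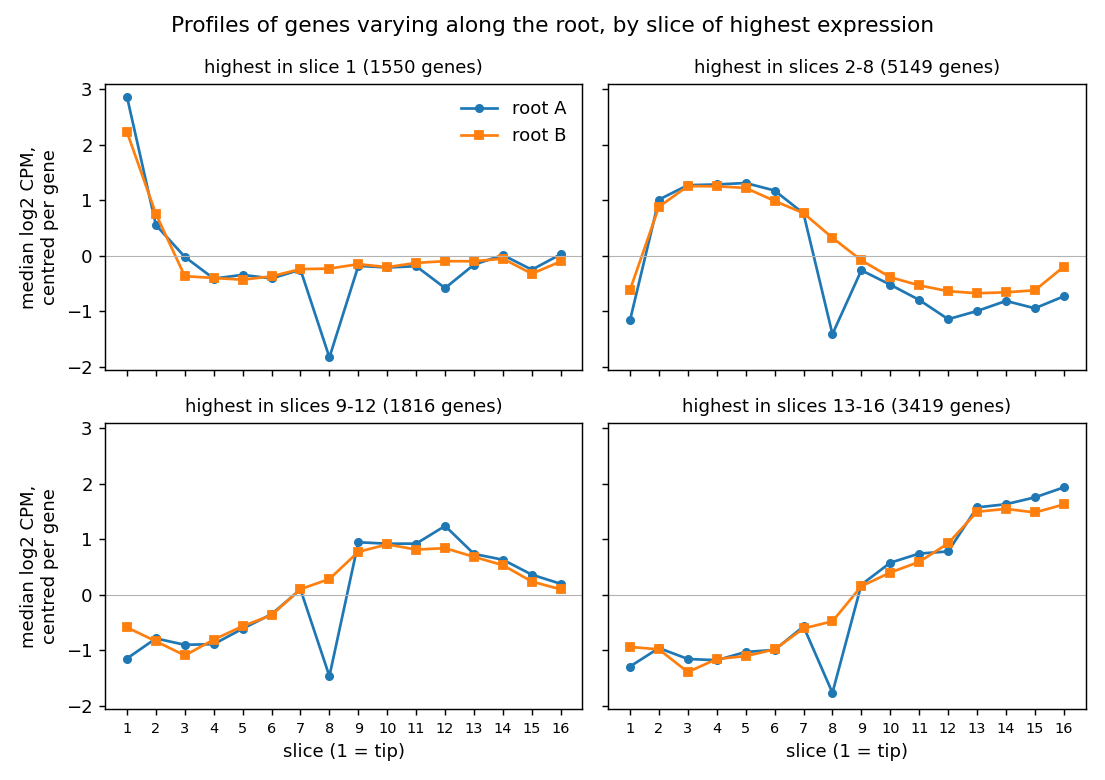
Median log2 CPM centred per gene (vertical axis) against slice number (horizontal axis) for the 4 groups of varying genes, with 1 line per root; the number of genes stands above each panel. Root A dips at slice 8 in every group, and from slice 1 to 2 the groups of slices 9 to 12 and 13 to 16 rise in root A (−1.15 to −0.79 and −1.29 to −0.96) and fall in root B (−0.59 to −0.84 and −0.94 to −0.98).

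A large part of the genes differed, in both directions, between slices 13 to 16 and slices 1 to 4, the slices farthest from the tip and those nearest to it. Of the genes tested, 5464 were higher at the back and 3992 lower, with median changes of 2.59 and −1.91 (log2). At least 8-fold changes were found for 2351 genes that were higher and 1003 that were lower. A group of 198 genes with a mean of at least 10 CPM at the back had no count in any of the 8 libraries of slices 1 to 4 (9617514 counts in all), and 123 genes with that mean at the front had none at the back (19443530 counts in all). Of the 9456 genes called, 99.3% changed in the same direction in both roots, against 82.9% of all genes tested; a call itself favours genes on which the roots agree. The median change over all genes shifted by −0.22 (log2) under DESeq2's size factors, with which 49.6% of the calls were higher at the back, against 57.8%. Which direction had more calls depended on the model, with 4854 genes higher and 5538 lower in DESeq2, 4935 and 5541 with blocks of 4 slices as groups, 2912 and 3811 in root A alone and 4058 and 4210 in root B alone. With slice 1 left out of the first block the directions were nearly even, with 5552 genes higher at the back and 5413 lower.

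The identifiers in the files carry no names and none matched the reference table, so only 4 genes are given by identifier. They had the highest and lowest changes from slices 1 to 4 to slices 13 to 16 among genes that met the rule for naming. Zm00001d038598 rose from 0.939 ± 1.03 CPM in slices 1 to 4 to 11050 ± 1658 CPM in slices 13 to 16 (SD, n = 8 libraries each; 11 against 184097 counts), a log2 change of 14.41 ± 0.64 (SE, edgeR, adjusted p = 1.49e-15). Its level climbed slice by slice, from 68.1 CPM in slice 7 of root A to 967 CPM in slice 9 and 13500 CPM in slice 13. Zm00001d017485 had no count in slices 1 to 4 and 1169 ± 278.5 CPM at the back (SD, n = 8), at least 4280-fold higher when 3 counts over the front group are taken as the floor (edgeR, adjusted p = 3.09e-17). Zm00001d041985 held 17900 CPM in slice 1 of root A and 16100 CPM in slice 1 of root B. It fell to 281 and 116 CPM in slice 4, and slices 13 to 16 together held 3 counts against 47290 in slices 1 to 4, a ratio of 24200 with a counting interval of 8270 to 117000 (edgeR, log2 change −13.43 ± 0.74 SE, adjusted p = 1.37e-12). Zm00001d004729 fell from 19385 counts in slices 1 to 4 to 4 in slices 13 to 16 (log2 change −13.38 ± 0.99 SE, edgeR, adjusted p = 2.64e-09). In root A it was highest in slice 1, at 8640 CPM. In root B it rose from 355 CPM in slice 1 to 1020 CPM in slice 3 before it fell. Whether near-identical copies share reads with these genes could not be looked up, and intervals and floors cover counting error only.

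**Figure D3:**
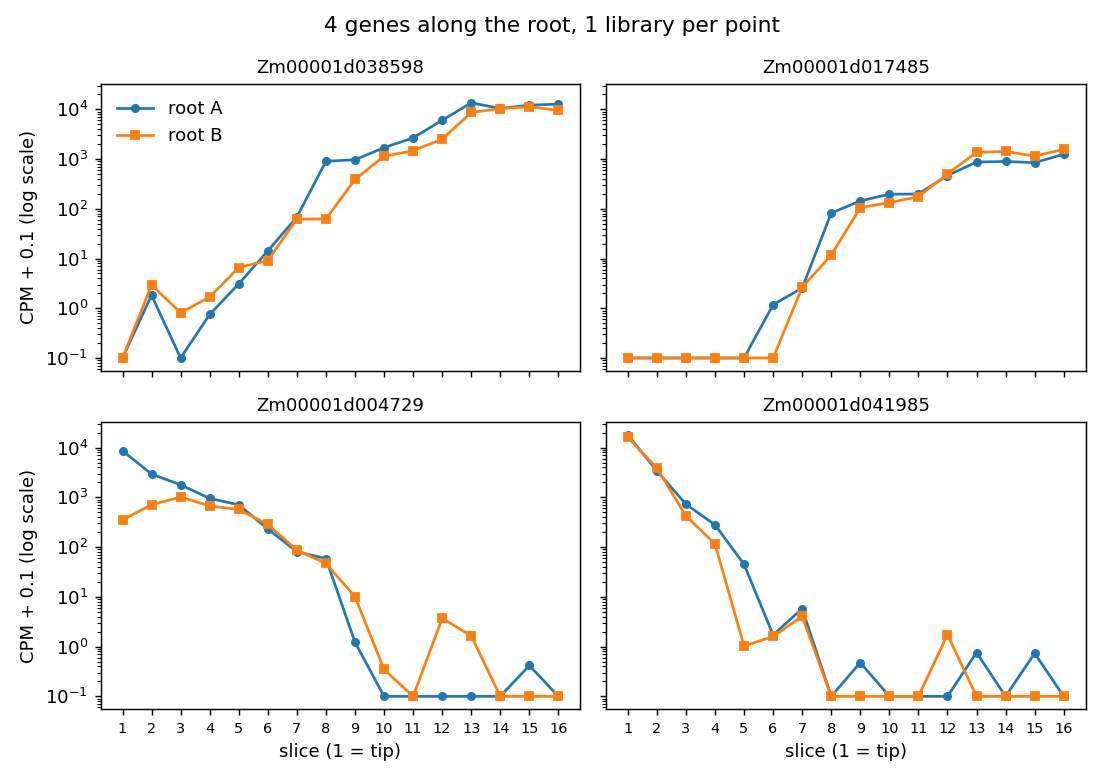
CPM plus 0.1 on a log axis against slice number for the 4 genes, 1 point per library, root A as blue circles and root B as orange squares. Zm00001d038598 and Zm00001d017485 climb towards the back in both roots, and Zm00001d004729 and Zm00001d041985 are at 3.61 CPM or less in every library behind slice 9.

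Among successive blocks of 4 slices, which follow the change with distance from the tip, the middle pair of blocks had the most calls. From slices 1 to 4 to slices 5 to 8, 1258 genes were higher and 649 lower. From slices 5 to 8 to slices 9 to 12, 4304 genes were higher and 4133 lower, with median changes of 1.71 and −1.92 (log2). From slices 9 to 12 to slices 13 to 16, 2351 genes were higher and 1489 lower. Over all genes tested, 62%, 77.3% and 69% changed in the same direction in both roots in the 3 comparisons, in that order. The balance of higher and lower calls depended on scaling in each: with DESeq2's size factors 751 genes were higher and 995 lower in slices 5 to 8, 3659 higher and 4830 lower in slices 9 to 12, and 3067 higher and 1027 lower in slices 13 to 16. In slices 9 to 12 it also depended on slice 8, with 4116 higher and 4996 lower without its root A library and 5521 higher and 1592 lower without its root B library. More genes were also lower than higher there without slice 11 of root B (4113 against 3972) or slice 12 of root B (4842 against 4042). With DESeq2 itself, 1218 genes were higher and 1360 lower in slices 5 to 8, and 3708 higher and 4410 lower in slices 9 to 12. With blocks of 4 slices as groups, 1100 genes were higher and 1351 lower in slices 5 to 8. The count for slices 5 to 8 against slices 1 to 4 was 1907, and 3183 without slice 8 of root B, with 1519 higher and 1664 lower.

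Slice 1, which holds the very tip, differed from the slices behind it in a large part of the transcriptome. Against slices 2 to 4, 2955 genes were higher in slice 1 and 2446 lower, with median changes of 2.6 and −3.41 (log2). At least 8-fold changes were found for 1112 genes that were higher and 1457 that were lower. In slice 1 of both roots, 20 genes had at least 10 CPM and 10 times the level of every library of slices 2 to 4, and 8 genes 10 times the level of every library of all other slices. In each library of slices 2 to 4, 309 genes had at least 10 CPM and 10 times the level of either library of slice 1. Of the 5401 genes called, 94.7% changed in the same direction in both roots, against 68.5% of all genes tested. The library of slice 1 of root A held 13740 genes at 1000000 counts and that of root B 17487; without slice 1 of root A, 2668 genes were called. DESeq2 turned the balance of directions, with 2755 genes higher in slice 1 and 3218 lower.

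Among single steps between neighbouring slices, the first had the most calls with all 32 libraries. From slice 1 to slice 2, 1426 genes rose and 968 fell, with medians of 4.07 and −2.68 (log2). From slice 2 to slice 3, 5 genes rose and 95 fell, and 8 genes changed from slice 3 to slice 4 and from slice 11 to slice 12. At 9 of the 15 steps edgeR called 0 genes, with 83 to 2099 genes at an unadjusted p under 0.05 and 0 to 13 called by DESeq2. From slice 7 to 8, 379 genes changed, and from slice 8 to 9, 561. Several of these counts moved by over 1.5 times with 1 library left out. From slice 2 to 3 the count was 3 without slice 2 of root B or either library of slice 3, 64 without either library of slice 7, and 208 or 230 without slice 8 of root A or B. From slice 11 to 12 it was 1489 without slice 12 of root B, 121 or 126 without slice 8 of root A or B, and 2 or fewer without most other libraries. From slice 12 to 13, 12 or 14 genes were called without slice 8 of root A or B, 26 without slice 13 of root B and 1140 without slice 12 of root B. From slice 3 to 4 the count ran from 1 to 10 over the libraries left out. Without slice 8 of root A the counts from slice 7 to 8 and from slice 8 to 9 were 4 and 22, and without slice 8 of root B 5215 and 5249. Without slice 9 of root A or root B the count from slice 8 to 9 was 4 or 40. Without either library of slice 7 the count from slice 7 to 8 was 0 in edgeR, with 1348 or 1370 genes at an unadjusted p under 0.05. From slice 1 to 2 the total of 2394 genes became 622 without slice 1 of root A, 855 without slice 2 of root A and 716 without slice 2 of root B, and without slice 1 of root B more genes fell than rose, 1072 against 788.

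Taking slices 2 by 2, an alternative chosen after the data were seen, gave fewer calls behind slices 3 to 5 than behind slice 2 or slices 7 and 8. Across the boundary behind slice 2, 3686 genes differed. By contrast, 180, 32 and 78 genes differed across the boundaries behind slices 3, 4 and 5. The counts then rose to 1732 behind slice 7 and 1792 behind slice 8, and were 604 behind slice 10 and 43 behind slice 14. Without slice 8 of root A the counts behind slices 2, 3, 4 and 5 were 4660, 241, 57 and 168, and those behind slices 7, 8, 10 and 14 were 1120, 1697, 1484 and 155. Without the 3 libraries with the fewest genes at 1000000 counts, slices 8, 1 and 12 of root A, they were 4381, 419, 104 and 391 behind slices 2 to 5 and 1862, 2680, 1022 and 443 behind slices 7, 8, 10 and 14. Slice 9 differed from slice 7 in 274 genes, and in 680 without slice 8 of root A.

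**Figure D4:**
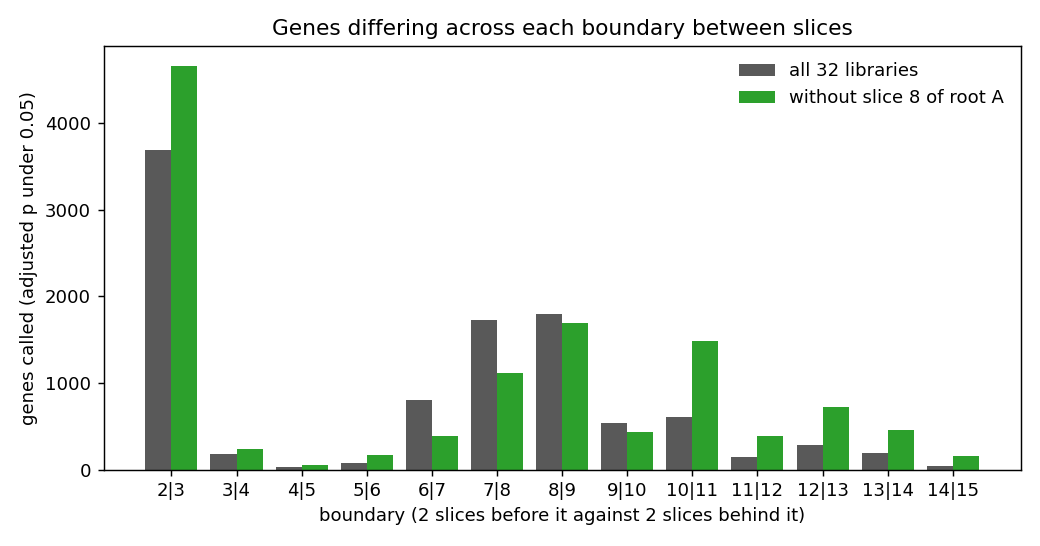
Genes called (vertical axis, edgeR, Benjamini-Hochberg adjusted) between the 2 slices in front of each boundary and the 2 slices behind it (horizontal axis), with all 32 libraries in grey and without slice 8 of root A in green. The counts are highest at the boundary behind slice 2 (3686) and rise again behind slices 7 and 8 (1732 and 1792), with 32 behind slice 4.

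Slices of the 2 roots matched by position. Over all 19587 genes tested, a set added after the data were seen because the varying genes are those on which the roots agree, the most similar slice of root B by Spearman correlation lay within 1 slice for each of the 16 slices of root A, and was the same slice for 12. The match of slice 8 was weak (same-slice correlation 0.06), and without slices 7 and 8 the match lay within 1 slice for 14 of 14 slices and was the same slice for 9. Over the varying genes the numbers were also 16 and 12. At matched slices 1964 genes differed between the roots, 1070 higher in root B and 894 lower, with median differences of 1.17 and −1.49 (log2). Without slice 8 of root A, 1346 were higher in root B and 1368 lower. Each side of this comparison is 1 root, so its p-values compare these 2 roots and no wider population. The count was 952 with an older dispersion step of the same test and 1107 among genes with a mean of at least 10 CPM. A test of the difference between the roots in the change from slices 1 to 4 to slices 13 to 16 called 6 genes, with 1273 at an unadjusted p under 0.05.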

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

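The tests in this part were chosen before their results were seen. The change from slices 1 to 4 to slices 13 to 16 differed between the roots in 6 genes (edgeR, root by block of 4 slices), 5 with a higher change in root B and 1 with a lower one. The differences ran from −5.31 ± 1 to 11.17 ± 1.6 (log2, SE), with adjusted p from 0.0255 down to 0.000196. In each of the 6 genes the fitted change went one way in root A and the opposite way in root B. The count was 4 without slice 13 of root B, 13 without slice 3 of root A, 14 without slice 8 of root A and 58 with no filter on low counts. Chance was not excluded: swapping the root letters at random within slices gave as many genes in 9 of 100 arrangements, the real one included. The highest other arrangement gave 213 genes, several times the real count. A spread of this kind points to some structure of the samples, which was not tested.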

How the results depend on the processing

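Values without the libraries of lowest complexity, with the older dispersion step and with slice 7 counted as 1 are from tests added after the data were seen. Of 111 alternatives to the counts that left out no single library, 96 stayed within 1.5 times; of 320 that left out 1 library, 308 did. These numbers take in the step from slice 1 to 2 and the sum over the steps, but not the other single steps. Of these, slice 11 to 12 moved by over 1.5 times with 29 libraries left out in turn, slice 7 to 8 and slice 8 to 9 with 4 each, and slice 5 to 6, 13 to 14 and 14 to 15 with none. For the steps named last the count was 0 with all libraries and without each, which shows no stability. The 4 genes given by identifier kept their direction and stayed called in all 180 alternatives run on them. They were picked for the most extreme changes, and most alternatives reuse most of the libraries, so this says little about other genes. The rule was also applied to slice 1 against slices 2 to 4, whose genes are not given here. Of those, 1 gene was not called with DESeq2 (adjusted p = 0.255). The letters pair the samples, and with the replicate block (paired by root) none of the following counts moved by over 1.5 times: 13139 genes varied, 9830 differed between slices 13 to 16 and 1 to 4, 2226 between slices 5 to 8 and 1 to 4, 9007 between slices 9 to 12 and 5 to 8, 4455 between slices 13 to 16 and 9 to 12, 5802 between slice 1 and slices 2 to 4, 2849 from slice 1 to 2, and 4482 over the 15 steps. The steps from slice 7 to 8 and from slice 8 to 9 gave 516 and 823 with the block. The remaining single steps were not compared with the block 1 by 1, and given the sum, at least 1 of them rose by over 1.5 times.

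Among genes with a mean of at least 10 CPM, where fewer genes were tested, 7426 varied, 2559 differed between slices 13 to 16 and 9 to 12, and 1107 between the roots. The older dispersion step gave 2541 and 952 for the last 2, and 1811 in place of 3450 calls summed over the 15 steps, for which DESeq2 gave 5661. The roots differed in 1182 genes with blocks of 4 slices as the covariate. For these the cause was not tested. With 1 root alone and the slices of a block as replicates, a change of both libraries and model, root A gave 562, 3847 and 625 genes for the steps between successive blocks of 4 slices and root B 799, 4744 and 1275. The difference between the roots in the back-to-front change gave 58 genes with no filter; the cause was not tested.

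Leaving out 1 library, with the other library of its slice assumed to vary like the rest and more genes passing the filter, gave 1343 to 3183 genes for slices 5 to 8 against 1 to 4 (highest without slice 8 of root B), 2668 to 6360 for slice 1 against slices 2 to 4 (lowest without slice 1 of root A), and 622 to 3465 from slice 1 to 2. For the difference between the roots in the back-to-front change, the count ran from 4 to 14. The sum over the steps ran from 1587 to 14310: 1587 without slice 2 of root B, 1811 without slice 2 of root A, 1892 without slice 1 of root A, 6354 without slice 12 of root B and 14310 without slice 8 of root B. In data simulated at the depth of these libraries, with the same spread in every slice, 9% of 4-fold and 40.9% of 8-fold changes from slice 1 to 2 were recovered. Depth itself was not varied. The alternatives planned for the gene lists were not run, since no list could be matched.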

Other observations

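Tests on slice 8 of root A, on the GRMZM5G identifiers, without the 3 libraries of lowest complexity, with slice 7 counted as 1 and with slices reordered within roots were chosen after the data were seen. Genes with an identifier of the GRMZM5G series, 140 of them tested, were called mostly in 1 direction at each comparison; no test of the set was run. Against slices 2 to 4, all 60 of them that were called (42.9%, against 27.5% of other genes) were lower in slice 1 (edgeR, median −2.49 log2 over the 140), as were all 61 called with DESeq2's size factors. Of the 140, 38 (27.1%, against 9.6% of other genes) were called in slices 5 to 8 against slices 1 to 4, all higher, 28 (20%, against 43.2%) in slices 9 to 12 against slices 5 to 8, all lower, and 41 (29.3%, against 19.5%) in slices 13 to 16 against slices 9 to 12, all higher. With DESeq2's size factors the counts were 13, 48 and 56 in the same directions, and without slice 8 of root A the middle step had 34 lower and 3 higher of 148 tested. Their share of all counts was 0.61% (95% Wilson interval 0.59 to 0.62) in slice 1 of root A and 1.16% (1.14 to 1.18) in root B. It was 3.35% and 3.97% in slice 4 and lay within 2.17% to 3.77% in slices 5 to 7, below slice 4 in each root. It was 1.2% and 1.99% in slice 9, and 4.34% and 4.59% in slice 16. In slice 8 of root A it was 14.37%, against 3.66% in root B.

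The genes that set slice 1 apart from slices 2 to 4 were often the ones that set the back apart from slices 5 to 8, a comparison of other libraries. Of 2955 genes higher in slice 1 and 5206 higher in slices 13 to 16 than in slices 5 to 8, 1387 were shared, against 785 for independent lists; of 2446 and 4944 lower genes, 1708 were shared, against 617. Opposite directions were rarer than for independent lists (179 against 746, and 192 against 650), and without the 3 libraries of lowest complexity 1257 and 1608 genes were shared against 715 and 642. If low complexity of the slice 1 libraries removed rare transcripts only, the pattern should vanish among abundant genes. With the back change taken against slices 5 to 7, the correlation of the 2 changes across genes was 0.407 in the 4897 most abundant genes (mean of at least 41.8 CPM) and 0.441 over all. This argues against loss confined to rare transcripts. It cannot decide on low complexity as such, since loss in slice 8 of root A was not confined to rare genes. There, 537 of 3546 genes with at least 100 counts in 3 other libraries had no count. Deviations of single roots are argued against by correlations of 0.348 and 0.428 when each change, taken in the same way, came from a different root. No biological explanation was tested.

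The libraries of slice 7 of roots A and B may share material. Across 11961 genes, the difference between the roots in a slice followed the mean difference in the other slices with a slope of 0.606 to 1.03 in every slice but slice 7, where it was 0.007. A chance match of similar roots would keep the slope within the range of the others, and the spread between the libraries, a coefficient of variation of 4.9% against 27.7% to 161.6% in the other slices, was also out of range. Mixing of tissue, RNA or libraries would each give this and stay open, and no biological explanation was tested. Counted as 1 library, slice 7 left 11261 varying genes and 1546 genes for slices 5 to 8 against slices 1 to 4.

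The library of slice 8 of root A may be of low complexity; what lowered it was not tested. It held 8262 genes at 1000000 counts, fewer than any other library, and of 3546 genes with at least 100 counts in slices 7 and 9 of root A and in slice 8 of root B, 537 (15.1%) had no count in it, while 0 had none in slice 10 of root A. Whether it was taken from another slice stays open: the most similar slice of root B was slice 8 (Spearman correlation 0.558 across genes), but slice 9 was at 0.555, slice 11 at 0.545 and slice 7 at 0.544, and slices 1 to 4 were at 0.4 to 0.458. Its GRMZM5G share above stays unexplained, and no biological explanation was tested.

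When libraries were reassigned at random, 1 of 100 arrangements, the real one, gave as many genes in each of 5 comparisons along the root. The real counts and the highest of the other arrangements were 11934 and 3123 for varying genes, 9456 and 3775 for slices 13 to 16 against 1 to 4, 1907 and 19 for slices 5 to 8 against 1 to 4, 8437 and 1849 for slices 9 to 12 against 5 to 8, and 3840 and 124 for slices 13 to 16 against 9 to 12. Libraries of a root share deviations, so the slices were also reordered at random within each root. As many genes came in 2 of 100 arrangements for slices 5 to 8 against 1 to 4, where the highest other gave 2427, and in 1 of 100, the real one, for the other 4 comparisons, with 2546, 3662, 411 and 1169 in the highest others for varying genes, slices 13 to 16 against 1 to 4, slices 9 to 12 against 5 to 8 and slices 13 to 16 against 9 to 12. Either way the share was under 0.05. Both kinds of reassignment treat neighbouring slices as exchangeable and put libraries of different positions into 1 group. Change along the root then counts as spread within groups, which lowers the calls. The shares show that the calls depend on the real order or pairing of the slices, and give no rate of chance calls. For the difference between the roots, the real letters gave 1964 genes, against 209 in the highest of the other swaps of letters. These swaps treat the slices of a root as separate units although their deviations are correlated (median 0.143), so the result says only that these 2 roots differ. Without the 3 libraries of lowest complexity 2741 genes differed between the roots.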
